A study of Bifidobacterium longum with 24 samples.

How the data were processed

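Total RNA from cultures grown in MRS medium with cysteine was labelled with a Genisphere 3DNA dendrimer kit and hybridised to 24 arrays of 2 colours, per the labels. Each array held RNA of 1 mutant and of the wild type NCC2705. The deposited scanner files give, per the file headers, unnormalized intensity per spot as quantified by ImaGene 5.6.0, with 1 file per dye, and the signal mean, the background median and the background SD were used. The series matrix holds the authors' log2 ratios per spot, and the submitters' processing notes name limma without a version.

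The direction of every ratio came from the dyes in the labels. Each mutant was combined with both dyes in 10 of the 12 biological replicates. In NCC2912 stationary HS45 both arrays had the mutant in Cy3, and in NCC2913 stationary HS50 both had it in Cy5. Set against the scanner ratios of mutant over wild type, the columns of the authors' table had slopes of 0.910 to 1.04 and correlations of 0.514 to 0.988, medians of -0.11 to 0.05, and values for 3937 to 9901 of the 10807 spots. Its scale (log2), centring near 0 and direction follow from this check, while its background treatment and exact normalization stay unknown.

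Intensities were corrected with normexp (offset 50) on the background median and normalized by loess within each array in limma 3.58.1 (statmod 1.5.0, R 4.3.3). The 712 control spots had weight 0 in the loess and were then left out, as were spots marked bad by the scanner software. Ratios were turned to mutant over wild type, and a dye effect per probe, estimated from the dye-swapped replicates, was subtracted. The probes of a gene, 6 in the median, were averaged. Among called genes, the probes of a gene did not all have the same sign for 3 of 56, 47 of 555 and 1 of 52 in NCC2912 (before heat shock, after 7 min, stationary) and for 2 of 50, 7 of 162 and 72 of 774 in NCC2913. A spot counted as above background where its signal exceeded the background median by 2 background SDs. A locus counted as above background on an array where any of its probes did, so a locus so counted can still be dim. A gene entered if any probe was above background on at least 2 arrays, which left out 0 of 1744 genes.

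The 2 technical arrays of a replicate were averaged (avearrays), which left 12 replicate values per gene. One limma fit with 6 group means and 6 residual degrees of freedom gave each mutant against the wild type, the mutants against each other and the changes between conditions. The SE of a gene comes from its spread pooled over all groups of the fit, with limma's moderation across genes, and not from the replicates of 1 group. A call is a Benjamini-Hochberg adjusted p under 0.05. For the wild type responses the channels were separated after loess and Aquantile normalization, and 18 replicate values in 9 groups of strain and condition were fitted together. There the wild type channels of the arrays of both mutants were averaged by HS label into 1 replicate, as if a label marked 1 wild type culture. The labels do not state this, and the deviations of the wild type channels on the arrays of the 2 mutants correlated at 0.367, 0.0126 and 0.0336 in the 3 conditions. The labels name 2 biological replicates per group, and do not say how the cultures were kept apart. Samples of both mutants share HS labels, and their deviations correlated at 0.0833, -0.0288 and 0.125 in the 3 conditions. As they were not over 0.1 in each condition, the labels were not used as pairs of mutant samples.

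Overlaps of calls between comparisons against the wild type are given beside the number for independent lists, and covariances of the log2 ratios beside those of simulated mutants without effect (100 simulations). The simulation gave no shared calls by its construction, so it sets no level for a count of shared loci. Runs of neighbouring loci were tested by shuffling the calls over the locus order 10000 times. The order is that of the locus numbers, with genome positions not used here. Slide, from the number in the scanner file names, and scan day were tested as batches: 13 slides and 10 scan days. The date in the file headers was taken as the scan day. Alternatives covered background correction, normalization, filter, dye correction, level of the fit, replicate block, slide, the authors' values, the samples in the fit and each replicate left out, all chosen before the data were examined, and scan day, a stricter filter, the stationary arrays left out and the wild type channels kept apart by mutant, chosen after.

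The genes named were to be the 10 largest rises and the 10 largest falls of each comparison with the same sign in both replicates (8 each way for the differences between mutants and conditions), plus members of fixed gene lists. The files pair the locus numbers with no names, and 0 of them matched the reference table, which covers the assembly of another strain. So the 2 largest rises and 2 largest falls are named by number, and the 17 gene lists fixed before the data were examined, heat shock regulons among them, were not run. A check on simulated data with 1744 genes, 200 of them changed, recovered 98.5% of log2 changes of 1 and 56.7% of changes of 0.5 for NCC2912 before heat shock. For NCC2912 in stationary phase it recovered 97.0% and 38.8%, for the difference between mutants 100% and 67.2%, for the NCC2912 change between conditions 86.6% and 20.9%, and for the wild type heat response 88.1% and 19.4%. At a log2 change of 2 all changed genes were recovered in each of these, with 4 to 12 false calls. The simulation gave every group the same spread, while the measured NCC2912 stationary replicates differed more than those before heat shock. The percentages for stationary phase may therefore be too high for the measured data.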

Results

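The series compared gene expression in Bifidobacterium longum, a gut bacterium, between the wild type strain NCC2705 and the mutants NCC2912 and NCC2913, under a title that concerns resistance to heat shock. Which genes the mutants carry changes in is not given in the sources used here, so no targeted gene could be checked. RNA came from exponential cultures at 37 °C before heat shock, from exponential cultures after 7 min at 50 °C, and from stationary cultures. Each of 24 arrays carried the RNA of 1 mutant and of the wild type from the same condition in opposite dyes. The 6 groups of mutant and condition held 4 arrays each, from 2 biological replicates with 2 technical arrays each, and the replicate (n = 2 per group) was the unit of every main test. The arrays measured 1744 features, of which 1721 were loci with NCC2705 numbers, 19 were open reading frames of ISBlo insertion sequences and 4 were RNA features. The files pair the numbered loci with no gene names, so loci appear by number, and only the largest changes are named.

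The 8 stationary arrays included the dimmest. Their median spot intensity, without background subtraction, ran from 20.5 to 489.5, except on the 2 arrays of NCC2913 HS45, where it ran from 708.0 to 1462. On the 16 exponential arrays it ran from 359.2 to 2717. On the stationary arrays 43.9% to 97.4% of the gene spots stood above background, against 54.0% to 99.2% on the exponential arrays. The NCC2913 HS45 arrays held the upper end with 91.1% to 97.4%. Across genes, which are not independent replicates, the mutant to wild type ratios of the 2 replicates correlated at 0.930 in NCC2912 and 0.773 in NCC2913 before heat shock, and at 0.947 and 0.496 after 7 min of heat shock. In stationary phase the correlation was 0.734 in NCC2913 and 0.223 in NCC2912. The SD across genes of a replicate's deviation from its group mean was 0.0686, 0.0909 and 0.247 in NCC2912 (before, 7 min, stationary). In NCC2913 it was 0.130, 0.230 and 0.286. Because the SEs pool the groups, SEs and p-values may be too small in stationary phase and in NCC2913 after 7 min of heat shock. In the tighter groups they may be too large. The number of arrays limits the precision of each value.

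The wild type response gives the background beside which the mutants stand. After 7 min of heat shock 415 loci rose and 377 fell in the wild type, 245 and 261 of them by over 2-fold. The largest rises were those of BL0516, by 5.46 ± 0.24 on the log2 scale (SE, 2 replicates per condition, adjusted p = 1.3e-12), and BL0517, by 4.98 ± 0.23 (adjusted p = 2.7e-12). The largest falls were those of BL0233, which fell by 6.50 ± 0.30 (adjusted p = 2.7e-12), and BL0232, which fell by 6.34 ± 0.32 (adjusted p = 8.5e-12), and both stood above background on 7 of the 8 arrays after heat shock. Called loci lay next to each other in the numbering more often than chance: 163 pairs of neighbours rose, against a mean of 95.6 in 10000 shuffles of the calls, and 172 fell, against 81.5 (permutation test, one-sided, p = 0.0001 each, the smallest that the shuffles can give). This comparison sets channels of different arrays against each other. Within the 6 slides that held both conditions BL0516 rose by 4.91 to 5.70 and BL0233 changed by -6.93 to -5.95. With slide or scan day as a random block in a fit of single arrays 1218 and 1211 loci were called.

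In stationary against exponential phase 515 loci rose and 572 fell in the wild type, 349 and 421 of them by over 2-fold. BL0188 rose by 6.15 ± 0.25 on the log2 scale (SE, 2 replicates per condition, adjusted p = 7.2e-13) and BL0571 by 5.48 ± 0.28 (adjusted p = 8.8e-12). BL0730 fell by 3.49 ± 0.26 (adjusted p = 2.0e-09) and BL0999 fell by 3.37 ± 0.26 (adjusted p = 3.1e-09). Neighbouring loci again moved together, with 241 pairs that rose against a shuffled mean of 148.0 and 323 that fell against 189.7 (permutation p = 0.0001 each, the smallest possible). No slide held both conditions, and BL0999 stood above background on 7 of the 8 stationary arrays.

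The first question was how NCC2912 differed from the wild type before heat shock. There 36 loci were higher and 20 lower than in the wild type, 17 and 11 of them by over 2-fold. BL0516 was 11.4-fold higher (log2 ratio 3.51 ± 0.22, SE, n = 2, adjusted p = 1.0e-06) and BL0517 9.80-fold higher (3.29 ± 0.17, adjusted p = 2.6e-07), the same loci that rose most in the wild type upon heat shock. BL0675 was 9.69-fold lower (-3.28 ± 0.41, adjusted p = 0.000369) and BL0344 4.93-fold lower (-2.30 ± 0.19, adjusted p = 1.4e-05). Called loci lay next to each other more often than chance, with 14 neighbouring pairs among the higher loci against a shuffled mean of 0.727 and 5 pairs among the lower loci against 0.225 (permutation p = 0.0001 each, the smallest possible). Of the 36 higher loci 13, and of the 20 lower loci 7, lay in runs of 3 or more. Without replicate HS20 the count fell to 21 and without HS38 to 24. It was 110 in a fit without the stationary arrays, and 140 and 147 with slide or scan day as a random block on single arrays, where each array counts as a unit.

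A run of 4 neighbouring measured loci that starts with BL0516 and BL0517 was singled out after its values were seen. Before heat shock all 4 were higher than in the wild type, with log2 ratios of 2.76 to 3.51 in NCC2912 and 3.69 to 4.62 in NCC2913. After 7 min of heat shock none of the 4 passed the test in either mutant, with ratios of -0.18 to 0.12 and -0.02 to 0.37. With median centring in place of loess, 3 of the 4 passed in NCC2913 at that time, with a median of 0.95. In stationary phase all 4 were higher, by 0.83 to 1.92 in NCC2912 and 0.65 to 1.01 in NCC2913, of which 1 passed in NCC2913 with median centring. The NCC2913 values there were 0.29 to 0.57 in replicate HS45 and 0.87 to 1.57 in HS50, and without HS50 0 of the 4 passed, while in NCC2912 3 passed without HS50. All probes of BL0517 were saturated on 1 of the 4 NCC2912 stationary arrays. In the wild type the run rose by 3.23 to 5.46 upon heat shock and by 3.11 to 4.97 in stationary phase. The drop of the ratio from before to after heat shock, tested itself, passed for all 4, from -3.49 to -2.67 in NCC2912 and from -4.63 to -3.32 in NCC2913.

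**Figure D1:**
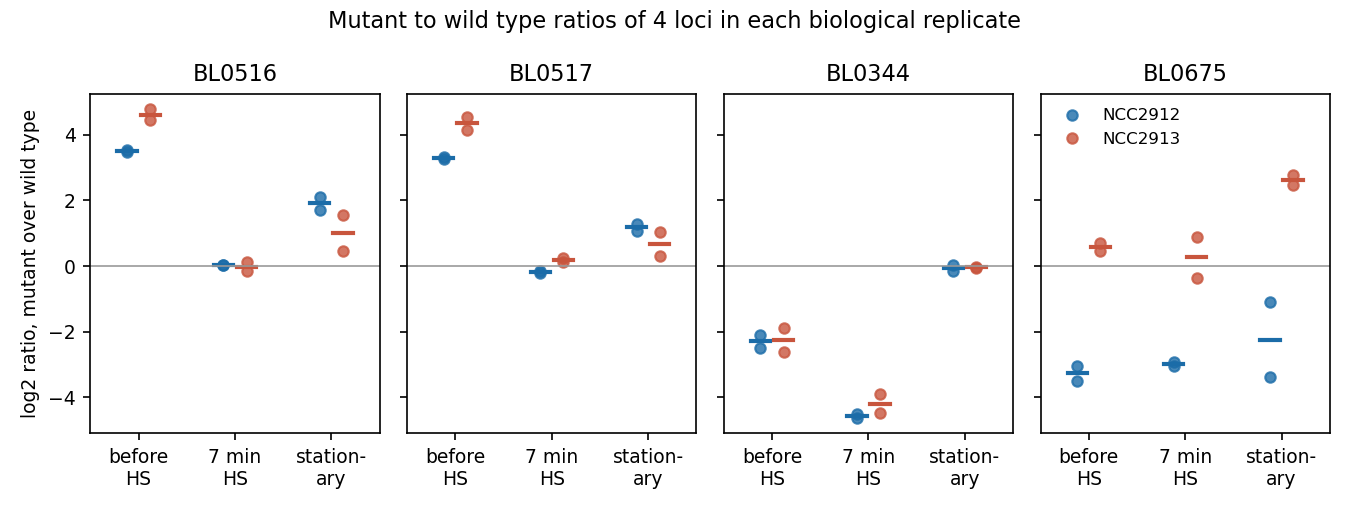
Log2 ratio of mutant over wild type (vertical axis) for 4 loci before heat shock (HS), after 7 min of heat shock and in stationary phase; points are the 2 biological replicates of each mutant and bars their means. BL0516 and BL0517 lay above 0 before heat shock and near 0 after it in both mutants, BL0344 lay below 0 in both before and after heat shock and near 0 in stationary phase, and BL0675 lay below 0 in NCC2912 in each condition.

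In NCC2913 before heat shock the largest rises were again those of BL0516 and BL0517, while BL0675 was not lower (0.57). Against the wild type 22 loci were higher and 28 lower, 17 and 12 of them by over 2-fold. BL0516 was 24.5-fold higher (log2 ratio 4.62 ± 0.22, SE, n = 2, adjusted p = 5.8e-08) and BL0517 20.5-fold higher (4.36 ± 0.17, adjusted p = 2.2e-08). BL0344 was 4.78-fold lower (-2.26 ± 0.19, adjusted p = 1.8e-05) and BL0400 4.62-fold lower (-2.21 ± 0.20, adjusted p = 3.6e-05, above background on 3 of the 4 mutant arrays). BL0344 belonged to a run of 4 neighbouring loci that were all lower in both mutants before heat shock, by log2 ratios of -2.30 to -1.18 in NCC2912 and -2.26 to -0.68 in NCC2913. Without replicate HS20 the count of 50 fell to 11 and without HS38 to 34. It was 33 on the authors' values and 26 with each mutant fitted alone, 105 without the stationary arrays, and 146 and 150 with slide or scan day as a block.

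The 2 mutants had 11 higher and 7 lower loci in common before heat shock, and 2 changed in opposite directions. Independent lists of these lengths would share 0.454 and 0.321. The log2 ratios of the mutants correlated across genes at 0.407, and their covariance of 0.0521 stood against 0.00271 in simulated mutants with no effect, and against 0.0159 if the wild type cultures were shared and varied as much as the mutants. Whether arrays of both mutants with 1 HS label used the same wild type culture is not stated. If so, part of the excess may come from it. Ratios of the 2 mutants from different HS labels were not set against each other.

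After 7 min of heat shock NCC2912 differed from the wild type at far more loci than before it. In NCC2912 261 loci were higher and 294 lower, 46 and 65 of them by over 2-fold. BL0194 was 6.44-fold higher (log2 ratio 2.69 ± 0.14, SE, n = 2, adjusted p = 1.9e-07) and BL1211 4.89-fold higher (2.29 ± 0.20, adjusted p = 1.6e-05). BL0344 was 23.7-fold lower (-4.57 ± 0.19, adjusted p = 4.5e-08) and BL0675 7.98-fold lower (-2.996 ± 0.41, adjusted p = 0.000410). The mean log2 level of BL0344 in NCC2912 was 6.77 there, low enough that its fold may not be exact. BL0194 was higher already before heat shock, at a mean log2 level of 11.2 in NCC2912 against 8.11 in the wild type. Within the 2 slides that held both conditions its ratio changed by -0.743 and -0.700 from before to after heat shock. Of the 19 insertion sequence reading frames, a group singled out after its values were seen, 11 were lower (16.4% of the other features were) and none was higher (15.1%), with a median log2 ratio of -0.57. With other scalings 8 to 11 of them were lower and none was higher. Without HS22 or HS39 the test called 1 of them, with medians of -0.57 and -0.51. Without replicate HS22 the count of 555 fell to 111 and without HS39 to 130. It was 369 with median centring and 841 without the stationary arrays.

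These differences ran against the wild type heat response. Of the 261 loci higher in NCC2912, 189 were among those that fell in the wild type upon heat shock, where independent lists would share 56.4, and of the 294 lower loci, 191 were among those that rose, against 70.0. Across genes the ratio correlated at -0.600 with the wild type response, and at -0.591 and -0.577 when ratio and response were taken from different replicates. The covariance was -0.371, where replicate error in the wild type RNA common to both sides could give at most -0.0376. The ratio also holds the wild type level after heat shock with a minus sign. A wild type response that the mutant did not share thus gives a negative value by itself, also between different replicates.

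In NCC2913 after 7 min of heat shock 76 loci were higher and 86 lower than in the wild type, 16 and 23 of them by over 2-fold. BL0628 was 4.11-fold higher (log2 ratio 2.04 ± 0.34, SE, n = 2, adjusted p = 0.00412) and BL0555 3.18-fold higher (1.67 ± 0.33, adjusted p = 0.00763). BL0344 was 18.3-fold lower (-4.20 ± 0.19, adjusted p = 1.2e-07) and BL0342 4.97-fold lower (-2.31 ± 0.19, adjusted p = 3.7e-05), both above background on 3 of the 4 mutant arrays. Their mean log2 levels in NCC2913, 7.17 and 6.71, were low, so these folds may not be exact. Of the higher loci 35 fell in the wild type upon heat shock (16.4 for independent lists), and of the lower loci 44 rose (20.5). The correlation with the wild type response was -0.354, and -0.159 and -0.380 between different replicates. Without replicate HS22 the count of 162 fell to 46, and BL0628 (adjusted p = 0.0745) and BL0555 (adjusted p = 0.169) no longer passed. It was 70 on the authors' values and also with each mutant fitted alone, 433 without the stationary arrays, and 480 and 509 with slide or scan day as a block.

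The mutants had 42 higher and 62 lower loci in common after heat shock, and 3 loci changed in opposite directions. Independent lists would share 11.4 and 14.5. The correlation across genes was 0.624, with a covariance of 0.135 against 0.00256 in the simulation.

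**Figure D2:**
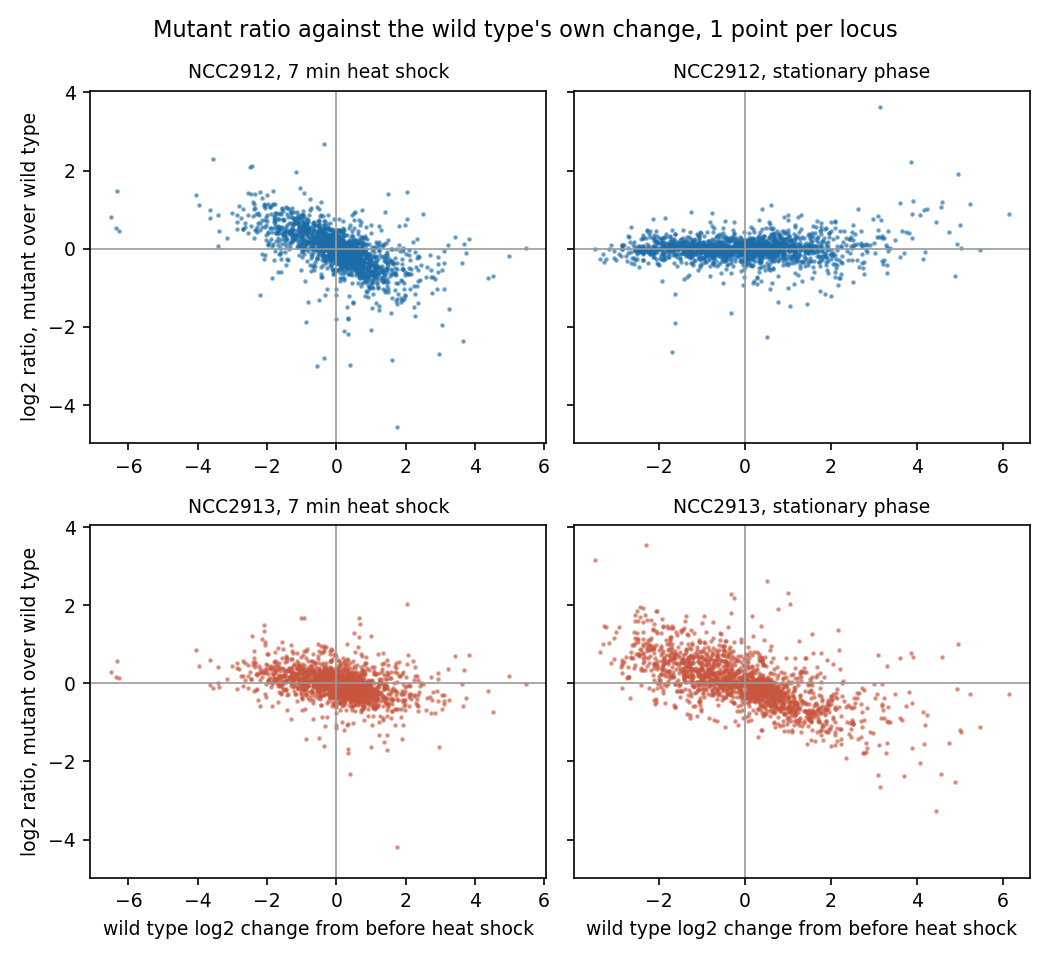
Each point is 1 feature, with the wild type log2 change from before heat shock on the horizontal axis and the log2 ratio of mutant over wild type on the vertical axis. The ratio ran against the wild type change in NCC2912 after heat shock (r = -0.600) and in NCC2913 in stationary phase (r = -0.648). The ratio holds the wild type level with a minus sign, so a wild type change that the mutant did not share gives a negative r by itself.

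In stationary phase NCC2912 had 24 loci higher and 28 lower than the wild type, 10 and 11 of them by over 2-fold. BL1126 was 12.5-fold higher (log2 ratio 3.64 ± 0.45, SE, n = 2, adjusted p = 0.00182), with replicate values of 2.26 in HS45 and 5.02 in HS50, and BL1251 was 4.69-fold higher (2.23 ± 0.24, adjusted p = 0.000945), with 1.53 in HS45 and 2.94 in HS50. BL0932 was 6.29-fold lower (-2.65 ± 0.21, adjusted p = 5.3e-05) and BL0675 4.75-fold lower (-2.25 ± 0.41, adjusted p = 0.0105), with replicate values of -3.40 in HS45 and -1.09 in HS50, and without HS45 BL0675 no longer passed (-1.09, adjusted p = 0.128). Of the 24 higher loci 19 were among those that rose in the wild type in stationary phase, against 7.09 for independent lists, and of the 28 lower loci 14 also rose (8.27) while 4 fell (9.18). Across genes the correlation with the wild type response was 0.117, and between different replicates 0.291 and -0.0695. Without HS45 the count was 55, of which 25 were among the 52, and without HS50 it was 76, with 35 among them. The count of 52 was 31 with median centring, 90 on the authors' values, 84 with each mutant fitted alone, and 118 and 130 with slide or scan day as a block.

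NCC2913 in stationary phase differed from the wild type at 402 higher and 372 lower loci, 106 and 86 of them by over 2-fold. BL1404 was 11.7-fold higher (log2 ratio 3.54 ± 0.18, SE, n = 2, adjusted p = 2.2e-07) and BL0730 8.97-fold higher (3.16 ± 0.16, adjusted p = 2.2e-07). BL1071 was 9.63-fold lower (-3.27 ± 0.29, adjusted p = 1.5e-05, with -3.93 in HS45 and -2.60 in HS50) and BL1126 6.27-fold lower (-2.65 ± 0.45, adjusted p = 0.000886). Of the higher loci 275 were among those that fell in the wild type in stationary phase (131.8 for independent lists), and of the lower loci 281 were among those that rose (109.9), with a correlation across genes of -0.648, and of -0.458 and -0.679 between different replicates. Of the 19 insertion sequence reading frames, singled out after their values were seen, 10 were lower and 1 was higher, with a median log2 ratio of -0.44. With other scalings 8 to 10 were lower. Without HS45 the test called 3 lower (median -0.19) and without HS50 12 (median -0.68). Without replicate HS45 the count of 774 fell to 314.

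The mutants had 8 higher and 12 lower loci in common in stationary phase, and 20 loci changed in opposite directions. Independent lists would share 5.53 and 5.97. Their ratios correlated across genes at -0.145, with a covariance of -0.0293 against 0.00257 in the simulation.

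**Figure D3:**
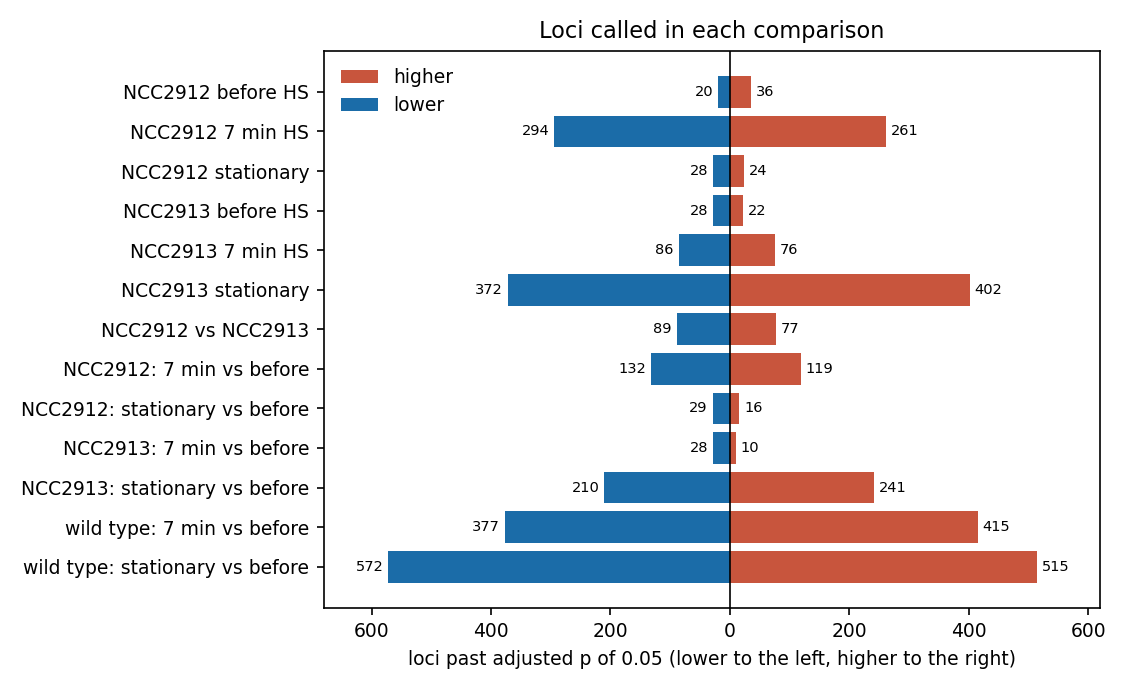
Number of loci past an adjusted p of 0.05 in each comparison, those higher to the right and those lower to the left of 0. NCC2912 differed from the wild type most after heat shock (261 and 294 loci) and NCC2913 in stationary phase (402 and 372 loci); HS stands for heat shock.

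Tested against each other over the 3 conditions, the mutants differed at 166 loci, 77 higher and 89 lower in NCC2912. BL0675 had the largest difference, lower in NCC2912 by a log2 difference of -3.99 ± 0.33 (SE, 6 replicates per mutant, adjusted p = 3.6e-05), and BL0033 came next among the lower loci at -1.93 ± 0.22 (adjusted p = 0.000257). BL1126 was higher in NCC2912 by 2.14 ± 0.37 (adjusted p = 0.00405) and BL0194 by 2.14 ± 0.11 (adjusted p = 7.5e-07). BL1126 rested on stationary phase: without the stationary arrays its difference was 0.07 (adjusted p = 0.721). No slide held both mutants. Within the 2 sets of arrays of both mutants scanned on 1 day in 1 condition, BL0194 was higher in NCC2912 by 2.98 and 3.38 and BL0675 lower at -1.95 and -3.97. The count fell to 62 without either NCC2912 replicate from before heat shock (HS20 or HS38), to 69 and 75 without NCC2912 HS22 and HS39, and to 95 and 91 without NCC2913 HS20 and HS38, and rose to 409 without NCC2913 HS50. It was 59 with median centring, 270 in the array-level fit with a dye term, and 356 and 443 with slide or scan day as a block.

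Whether the mutant effect changed with the condition was tested directly. In NCC2912 the ratio to the wild type differed between 7 min of heat shock and before at 251 loci, 119 of them with a higher and 132 with a lower ratio after heat shock. The ratio of BL1667 went up by 2.29 ± 0.35 (log2, SE, 2 replicates per condition, adjusted p = 0.00203) and that of BL1211 by 2.23 ± 0.29 (adjusted p = 0.000709). The ratio of BL1164 fell by 3.49 ± 0.21 (adjusted p = 2.4e-06) and that of BL0516 fell by 3.49 ± 0.31 (adjusted p = 5.0e-05). Within the 2 slides that held both conditions the change was -3.79 and -3.18 for BL1164 and -3.67 and -3.37 for BL0516. The count fell to 45 and 53 without HS20 and HS38, and to 54 without either HS22 or HS39. It was 136 on the authors' values, 525 with each mutant fitted alone, 573 without the stationary arrays, and 685 and 764 with slide or scan day as a block.

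In NCC2913 the same contrast gave 38 loci, 10 with a higher and 28 with a lower ratio after heat shock. The ratio of BL0516 fell by 4.63 ± 0.31 (log2, SE, 2 replicates per condition, adjusted p = 2.9e-06) and that of BL0517 fell by 4.17 ± 0.24 (adjusted p = 1.9e-06). The ratio of BL1218 went up by 1.503 ± 0.24 (adjusted p = 0.00477) and that of BL0532 by 1.33 ± 0.24 (adjusted p = 0.0137). Within the 4 slides that held both conditions BL0516 changed by -5.08 to -4.16 and BL0517 by -4.46 to -3.89. Without replicate HS20 neither BL1218 (adjusted p = 0.0782) nor BL0532 (adjusted p = 0.0520) passed, and BL0532 was also lost without HS38 (adjusted p = 0.144), without HS39 (adjusted p = 0.0570), with median centring (adjusted p = 0.0763) and with each mutant fitted alone (adjusted p = 0.0974). On the authors' values BL1218 did not pass (adjusted p = 0.110). The count was 13 and 20 without HS20 and HS38, 20 on the authors' values, 16 with each mutant fitted alone, 22 with no background correction, 25 with median centring, 57 without HS39, 78 with a dye term, 144 without the stationary arrays, and 350 and 342 with slide or scan day as a block.

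Between stationary phase and exponential phase before heat shock the NCC2912 ratio differed at 45 loci, 16 with a higher and 29 with a lower ratio in stationary phase. The ratio of BL1126 went up by 3.88 ± 0.64 (log2, SE, 2 replicates per condition, adjusted p = 0.00548) and that of BL0344 by 2.24 ± 0.27 (adjusted p = 0.000577), though in stationary phase BL0344 stood above background on 2 of the 4 mutant and 6 of the 8 wild type arrays. The ratio of BL0454 fell by 3.31 ± 0.39 (adjusted p = 0.000515) and that of BL0194 fell by 2.91 ± 0.20 (adjusted p = 1.1e-05). The change of BL1126 was 5.26 without HS45 and 2.497 without HS50. It did not pass without HS20 (adjusted p = 0.0599), nor BL0344 on the authors' values (adjusted p = 0.188). The count was 15 and 20 without HS20 and HS38, 25 with median centring, and 93 and 108 with slide or scan day as a block, and no slide held both conditions.

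In NCC2913 the same contrast gave 451 loci, 241 with a higher and 210 with a lower ratio in stationary phase. The ratio of BL0730 went up by 2.89 ± 0.23 (log2, SE, 2 replicates per condition, adjusted p = 2.0e-05) and that of BL0344 by 2.22 ± 0.27 (adjusted p = 0.000285), with BL0344 above background on 2 of the 4 stationary mutant arrays. The ratio of BL0517 fell by 3.69 ± 0.24 (adjusted p = 7.4e-06) and that of BL0516 fell by 3.61 ± 0.31 (adjusted p = 2.7e-05). The count was 124 and 154 without HS20 and HS38, 207 without HS45 and 731 without HS50. It was 216 with each mutant fitted alone, and 772 and 713 with slide or scan day as a block, and no slide held both conditions.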

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

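Of the tests below, 7 were chosen only after the result was seen: those on error in the wild type response and on the level reached for NCC2912, all 3 on NCC2913 in stationary phase, that on the dye effect in uncorrected ratios of NCC2912, and the splits within conditions. Reading the NCC2912 stationary correlations with an interval across genes was also chosen after.

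The mutants differed from each other at 166 loci, and the ratio to the wild type changed with the condition at 251 loci (NCC2912, heat shock), 45 (NCC2912, stationary phase), 38 (NCC2913, heat shock) and 451 (NCC2913, stationary phase). Each is a difference between groups past its own test. For the 166, the 4 replicates of each condition were split 2 and 2 under the same model and contrast. Of 100 such splits 3 gave as many. The 2 besides the real one, with 254 and 217 loci, kept the replicates of each mutant together and exchanged the mutants in 1 condition (stationary phase and heat shock). The same exchange before heat shock called 30, fewer than some splits that mixed the mutants, which called up to 110. A simpler model, with condition and 1 mutant term, called 7 genes. Of 100 splits of the 12 replicates into equal groups only 1, the real one, gave as many, with 1 in the highest other. Under both models, splits that mix the mutants put any difference between them into the residual spread, which lowers their counts. Such splits set no level for chance, so chance is excluded neither for the 166 nor for the 7.

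NCC2912 moved less upon heat shock than the wild type over genes picked by the wild type, those that moved by over 1 log2 unit in 1 wild type replicate. The slope on that replicate was 0.635 and 0.606 for NCC2912 and 0.982 and 0.948 for the other wild type replicate. Of these genes 82.9% and 91.8% moved less in NCC2912. Any difference between the strains in which genes respond lowers a slope on the wild type. Genes picked by NCC2912 were not tried, so a smaller response as a whole is not shown. NCC2913 went the same way, with slopes of 0.878 and 0.749 and 61.0% and 74.4% of the genes moving less, and the difference between the mutants' slopes was not tested. Error in the wild type response is argued against by the slope of the other wild type replicate, which stayed above that of NCC2912 by at least 0.342. Over the genes of middle level the difference was at least 0.320. That level is a mean over all samples, so genes at the floor or ceiling in 1 condition can remain among them. A floor or ceiling of the signal therefore stays open. A change before heat shock is argued against as the whole source by the level that NCC2912 reached, measured from the wild type before heat shock, whose slope lay below that of the wild type by at least 0.265, while leaving out the genes called before heat shock (0.313) excludes nothing, since smaller changes stay in. A damped or delayed response in NCC2912 is a candidate explanation that was not tested, and neither were differences in heating between the cultures.

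NCC2913 moved less in stationary phase over genes picked by the wild type in the same way, with slopes of 0.670 and 0.566 against 0.914 and 1.02 in the wild type. As above, a smaller response as a whole is not shown. The responses of both wild type replicates were taken from the same wild type mean before heat shock, whose error may raise the wild type slope. Dim arrays are argued against by NCC2912, whose stationary arrays were dimmer at the same HS label (20.5 to 79.2 against 81.1 to 156.3 in HS50, 305.3 to 489.5 against 708.0 to 1462 in HS45), and whose slope lay below that of the wild type by at most 0.0778, against 0.244 and 0.456 in NCC2913. The missing dye swap is argued against by the swapped replicate HS45, where the difference was 0.456. Cultures of NCC2913 less far into stationary phase cannot be told apart from a mutant effect, because the weaker of the cross-replicate correlations with the wild type response was -0.458, short of the -0.5 set for that explanation, and no growth data were used here.

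The 2 NCC2912 stationary replicates correlated at only 0.223, and replicate HS50 correlated with the wild type stationary response at 0.291 and HS45 at -0.0971. The dye effect estimated in the other groups is argued against, since in ratios not corrected for dye it correlated with the difference between replicates at -0.142. The replicates correlated at 0.246 in those ratios. In corrected ratios the correlation with the dye effect was 0.0239 beside this value, and 0.140 in the test chosen before. Both decide nothing, as the correction removes that effect. Weak signal stays open: over the 436 genes brightest on average the replicates correlated at 0.262, with a 95% interval of 0.172 to 0.347 across genes that takes in the 0.3 set as its limit. A difference in growth stage between the replicates may contribute as well (correlation -0.307 with the wild type stationary response), and neither can be told apart from the other.

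Control spots that belong to no comparison gave signal on most arrays. The median intensity over both channels of the arrays was 3351 on the C4-Lucif spots and 40197 on the C5-KmR spots, against 20.5 on the 79 negative control spots. On 2 NCC2912 arrays of 1 slide the C5-KmR spots stayed below that level, with 5.99 for the mutant and 1.81 for the wild type before heat shock (HS20, mutant in Cy5) and 1.37 and 2.12 after it (HS22, mutant in Cy3). The mutant to wild type ratio of C4-Lucif was -4.26 (log2) on 1 NCC2912 array from before heat shock (HS38, mutant in Cy5), next lowest -0.90. That of C5-KmR was -8.19 on 1 NCC2912 array after heat shock (HS22, mutant in Cy5), next lowest -0.67. The wild type median of C5-KmR on that array, 65354, lay above the 65000 counted as saturated, so -8.19 is not an exact value.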

How the results depend on the processing

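Scan day, the stricter filter, the fits without the stationary arrays and the wild type channels kept apart were chosen after seeing the data. The direction of every named locus held in all alternatives run. Of their values 594 stayed past the threshold and 5 did not under other settings, and 184 did and 8 did not with a replicate left out. Of the counts 104 lay within 1.5 times under other settings and 46 did not, and 22 and 26 with a replicate left out. The filter on dim probes removed 0 genes, so the fit without it tests nothing; a first stricter filter also removed 0 and was redefined before any fit, and the one used kept 1546 genes (without BL0342).

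Counts that moved, in the order NCC2912 before heat shock (main 56), 7 min (555), stationary (52), NCC2913 before (50), 7 min (162), between mutants (166), NCC2912 heat contrast (251), NCC2912 stationary contrast (45), NCC2913 heat contrast (38), NCC2913 stationary contrast (451) and wild type heat (792), were as follows. The causes were not tested except where stated. With no background correction the NCC2913 heat contrast gave 22. With median centring NCC2912 gave 369 at 7 min and 31 in stationary phase, the mutants 59, and the contrasts 25 (NCC2912 stationary) and 25 (NCC2913 heat). With a dye term at array level the mutants gave 270 and the NCC2913 heat contrast 78. Slide as a block gave 140 and 118 for NCC2912 before and stationary, 146 and 480 for NCC2913 before and at 7 min, 356 between mutants, 685, 93, 350 and 772 for the contrasts and 1218 for the wild type. Scan day gave 147, 130, 150, 509, 443, 764, 108, 342, 713 and 1211 in that order; both count 24 arrays as units, which by construction raises counts. The authors' values gave 90 (NCC2912 stationary), 33 and 70 (NCC2913 before and 7 min), 136 and 20 (heat contrasts of NCC2912 and NCC2913). Each mutant alone, with fewer replicates, gave 1.1e+02 (63 higher and 51 lower) for NCC2912 before and 84 for NCC2912 stationary, 525 (NCC2912 heat contrast), 26 and 70 (NCC2913 before and 7 min), 16 and 216 (NCC2913 contrasts). Without the stationary arrays the counts were 110, 841, 105 and 433 for NCC2912 and NCC2913 before and at 7 min, and 573 and 144 for the heat contrasts.

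With a replicate left out, which leaves a lone replicate assumed to vary like the other groups, counts ran from 21 to 24, 111 to 130 and 55 to 76 (NCC2912 before, 7 min, stationary, where only 25 and 35 of the main 52 were among them), 11 to 34, 46 to 190 and 314 to 854 (NCC2913), 62 to 409 (between mutants), 45 to 54, 15 to 67, 13 to 57 and 124 to 731 (contrasts in the order above), and 571 to 597 and 891 to 955 (wild type heat and stationary).

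Under other scalings the share of higher calls moved by over 10 points in NCC2913 before heat shock, from 44.0% to 57.9% with no background correction, 54.3% with median centring and 60.6% on the authors' values. It moved in NCC2912 stationary from 46.2% to 32.3% with median centring, in the NCC2912 stationary contrast from 35.6% to 48.6% on the authors' values, and in the NCC2913 heat contrast from 26.3% to 12% with median centring and 5% on the authors' values. The median of all genes lay between -0.09 and 0.06 under these scalings. Under other fits it moved as far in NCC2912 before heat shock, from 64.3% to 47.9% (slide), 49.0% (scan day) and 52.7% (without the stationary arrays), in the NCC2913 heat contrast to 43.6% (dye term), 47.7% (slide), 47.95% (scan day), 47.9% (without the stationary arrays) and 6.25% (each mutant alone), and in NCC2913 before to 57.7% (each mutant alone). With a replicate left out it moved in NCC2913 before to 63.6% and at 7 min from 46.9% to 58.7%, and in the contrasts to 20% and 55.8% (NCC2912 stationary) and to 0%, 15% and 42.1% (NCC2913 heat).

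With the HS label as a replicate block no count moved by over 1.5 times (for example 57 and 548 for NCC2912 before and at 7 min, 770 for NCC2913 stationary, 178 between mutants). The deviations of samples that share a label correlated at 0.0833, -0.0288 and 0.125, over 0.1 in stationary phase only, so mutant samples were taken to share only a number. Wild type channels were merged by label all the same, and kept apart by mutant, with more replicates, they gave 1021 loci for heat shock and 1301 for stationary phase. In the fit of separate channels, where a label also joins both channels of an array, the block correlation was 0.316. Not run were the authors' values for the wild type comparisons, each mutant alone for the difference between mutants, and the gene lists, whose names could not be matched to locus numbers. Signal over background limits the stationary results, with as few as 43.9% of gene spots above it in 1 channel of an NCC2912 array.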

Other observations

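The groups below were chosen after their values were seen. BL0675 was lower in NCC2912 in all 3 conditions (-3.28, -2.996 and -2.25 on the log2 scale), though in stationary phase it did not pass without HS45 (-1.09), and in NCC2913 its ratios were 0.57, 0.26 and 2.62. In NCC2912 1 other locus, BL1657, was lower in all 3 (-1.22, -0.99 and -1.03), and none was higher. In NCC2913 5 loci were higher and 4 lower in all 3 conditions, among them BL1404 (1.43, 1.67 and 3.54) and BL0628 (2.14, 2.04 and 0.96), and BL0400 (-2.21, -1.69 and -0.72), which stood above background on 3, 4 and 2 of the 4 mutant arrays. These 3 loci went the same way in NCC2912, with ratios of 0.29, 0.73 and 0.26 for BL1404. There BL0628 had 1.53, 0.77 and 1.12, and BL0400 had -1.97, -1.78 and -0.22.

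Loci changed in the mutants before heat shock were set against the wild type heat response. Of the 36 loci higher in NCC2912, 18 rose in the wild type upon heat shock (8.57 for independent lists) and of the 22 higher in NCC2913, 12 did (5.24). Of the 20 loci lower in NCC2912, 9 fell in the wild type (4.32) and 3 rose (4.76), but of the 28 lower in NCC2913, 11 rose (6.66) and 5 fell (6.05). Across genes the correlation was 0.233 in NCC2912 and 0.121 in NCC2913, and 0.226 to 0.227 and 0.108 to 0.117 when ratio and response came from different replicates. The covariances were 0.0937 and 0.0481, where replicate error in the wild type RNA common to both sides could give up to 0.0376.

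Of the 19 insertion sequence reading frames, 9 were higher in the wild type upon heat shock (23.5% of the other features were) and 10 in stationary phase (29.3%). Neither excess passed (one-sided Fisher test, adjusted p = 0.177 and 0.185). Upon heat shock 2 of the 19 fell, and in stationary phase 0 did. Copies of an insertion sequence can hybridise to the same probes, so the 19 values are not independent. tmRNA-ssrA, an RNA named in the files, passed in none of the 13 comparisons, with log2 values of -0.30 to 0.40 and a lowest adjusted p of 0.183. Its mean log2 levels, 15.1 to 15.6, were high enough that saturation of single probes may have compressed these values.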
